A study of Homo sapiens with 12 samples.

How the data were processed

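KBM-7 cells were crosslinked with formaldehyde and their chromatin was sheared to about 300 bp before immunoprecipitation, per the labels' protocols. The 12 samples are 9 immunoprecipitated libraries, 1 for each mark, and 3 inputs. By the labels, 1 input goes with H3K9ac, H3K4me3 and H3K79me2, another with H3K27ac, H3K4me1, H3K4me2, H3K36me3 and H4K16ac, and the last with H3K27me3. The inputs entered no comparison.

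The authors deposited 1 list of called intervals with a chromosome, a start, an end and the name of a mark, and without any count, score or signal. The submitters' processing notes name cutadapt, Bowtie2, MACS and the build GRCh38; versions, thresholds, roles and filters are not given in the sources used here, nor is the input used for each call. The depth per library is therefore unknown, and the precision of a set cannot be judged from reads. The intervals of 6 marks start on a grid of 150 bp. Those of H3K36me3, H4K16ac and H3K27me3 start on a grid of 500 bp, and 84.3% of the H3K27me3 intervals are 1000 bp long and overlap their neighbours. Starts in the file follow a mix of conventions, counted from 0 or from 1; they were brought to 1 convention by their remainder on the 50 bp grid. The labels H3K36me3 and H4K16ac hold 45695 identical intervals and were used as 1 set, which leaves 8 sets and 28 pairs. Intervals under 1 further label matched no sample and were not used. Chromosomes 1 to 22 and X were used.

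Overlapping or directly adjacent intervals of a mark were joined into regions, where the plan had kept them apart. Genes came from a RefSeq table of the same build, with 19974 protein-coding genes and no strand. The starts of transcription were therefore unknown, and windows of 1 kb around both annotated ends of each gene took the place of the planned windows around starts. A region counted as being at a gene end when it overlapped a window by at least 1 bp. Observed overlaps were set against 100 circular shifts along each chromosome. Assembly gaps were not used here as such; 33 stretches of at least 1 Mb that the file marks as free of any interval, 181 Mb in all, were left out of the shifts in their place. A value was called where it lay outside all 100 shifts. These choices departed from the planned design because of what the file and the annotation hold, and were made before any overlap was computed.

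The 20 gene lists had 509 entries, of which 506 matched the annotation; H19, KCNQ1OT1 and MEG3 did not. For each list and mark, the number of members with the mark was ranked among 10000 random lists of the same size, and lists below percentile 2.5 or above 97.5 were called. Covered bp within 5 kb of a gene were counted over both ends together. Gene bodies were genes of at least 5 kb in 20 bins; direction was taken from H3K4me3 where exactly 1 end held it. Distal regions lay farther than 2 kb from the ends of genes of every biotype. Broad domains were ranked by width, or by covered bp for H3K27ac merged over gaps of up to 12.5 kb. Since each mark has 1 library, no p-value was computed; shares have Wilson 95% intervals, which cover counting error only.

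The genes named were fixed by rule before the data were examined: for each list and mark, up to 4 marked members with the most covered bp within 5 kb and, where 4 or fewer members went against the majority, all of these; the 10 widest of each domain ranking; the HOX clusters as groups; and BCR and ABL1. The text names a selection of these. CISH, PGK1, RCC1 and ZEB2 as added under the H3K4me3 ranking, and MYC and RAG1 in the closing observations, were singled out after their values were seen.

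For H3K27ac, random lists were also matched on H3K9ac cover within 5 kb. This was done by 5 classes of equal size (genes without any cover apart) or by the 100 nearest genes. Widths were compared with 1000 draws of regions, each weighted by its width plus the median H3K27ac width of 600 bp. The overlap and list functions were tested on simulated data. Of 20 simulated pairs without shared sites, 0 were called, and of 20 with a planted share of 20%, 20 were called above. These pairs had the widths of H3K4me3 and H3K9ac and were counted on chromosomes 19 to 22. Apart from the planted sites they were placed at random, without clustering in gene-rich sequence. They therefore cannot show whether such clustering alone leads to calls. Of 500 random lists, 15 were called above and 17 below, and 440 of 500 lists with a share of 80% were called above.

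The alternatives chosen at the same time were wider regions (those at or above the median width of their set, as the file gives no score), other windows, gaps, overlaps and gene lengths, and independent placement in place of shifts. Added after the data were seen were intervals as deposited, the whole gene span, isolated genes, shifts without left-out stretches, random runs of consecutive genes, and all results without chromosome 8 and the 61 to 90 Mb part of chromosome 15. The 2-copy state of those stretches comes from general knowledge of the line. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used.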

Results

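The series asked where 9 histone modifications lie along the genome of KBM-7 cells, a near-haploid human line derived from chronic myeloid leukaemia. Chromatin immunoprecipitation followed by sequencing was done once for each of H3K4me1, H3K4me2, H3K4me3, H3K9ac, H3K27ac, H3K27me3, H3K36me3, H3K79me2 and H4K16ac. A further 3 libraries were inputs. There was 1 library per mark and no replicate, so no difference below could be set against replicate error. The deposited data were called intervals without a read count, score or signal, so the depth of each library is unknown. The labels H3K36me3 and H4K16ac held the same 45695 intervals, which are treated below as 1 set under both names. All coordinates are GRCh38. Wilson 95% intervals cover counting error only, and every comparison describes these libraries.

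H3K27me3, the mark laid down by Polycomb repressive complexes, covered far more of the genome than any other mark. Its 117702 regions spanned 914 Mb, or 32.1% of the usable sequence, with a median width of 5000 bp. The H3K36me3/H4K16ac set covered 8.51% in 37321 regions of 3500 bp median width. H3K4me2 followed with 50132 regions and 2.73%, H3K79me2 with 31865 regions and 2.40%, and H3K4me1 with 42673 regions and 1.52%. H3K9ac and H3K4me3 covered 0.794% and 0.553%, in 19505 and 14803 regions with a median of 900 bp each. H3K27ac was the sparsest set, with 3368 regions of 600 bp median width on 0.0853% of the sequence. At least 1 set covered 44.2% of the usable sequence. Since the number of regions follows the caller and an unknown depth, these totals do not rank the abundance of the marks.

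H3K4me3 and H3K9ac lay mainly at the ends of genes. Of the H3K4me3 regions, 68.4% (67.6 to 69.1) overlapped a window of 1 kb around an annotated end of a protein-coding gene, 14.99 times the mean of 100 circular shifts. The share was 60.4% (59.8 to 61.1) and 12.7-fold for H3K9ac, 36.02% (34.4 to 37.7) and 8.88-fold for H3K27ac, and 35.6% (35.2 to 35.99) and 7.13-fold for H3K4me2. H3K79me2, H3K4me1 and the H3K36me3/H4K16ac set stood at 4.08-fold, 2.77-fold and 1.68-fold. H3K27me3 regions were under-represented there, at 7.24% (7.09 to 7.39) and 0.738-fold. At genes with no other gene within 5 kb this was much weaker, at 0.935-fold, and the H3K36me3/H4K16ac set stood at 1.19-fold. By gene, H3K4me2 marked 13529 of 19974, H3K9ac 11003, H3K4me3 10253, H3K79me2 7167, H3K36me3/H4K16ac 6949, H3K27me3 6499, H3K4me1 4605 and H3K27ac 1281. Each set lay outside all 100 shifts. The annotation gives no strand, so start and end of a gene were not told apart. With the whole gene span in place of its ends, the folds were 1.97 for H3K4me3, 1.79 for H3K9ac, 1.51 for H3K27ac, 1.497 for H3K4me2, 1.99 for H3K79me2 and 1.41 for H3K4me1.

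H3K4me1, H3K4me2, H3K4me3, H3K9ac, H3K27ac and H3K79me2 shared sequence with each other, and H3K27me3 was set apart from all other sets. H3K4me3 and H3K9ac shared 13.0 Mb, 87.7 times the mean of the shifts, and 82.8% (82.1 to 83.4) of H3K4me3 regions overlapped H3K9ac. Of the H3K27ac regions, 77.1% (75.7 to 78.5) overlapped H3K9ac, at 76.0-fold in shared bp, and 96.9% (96.2 to 97.4) overlapped H3K4me2. H3K4me1 overlapped H3K4me2 at 76.2% (75.8 to 76.6) of its regions but H3K4me3 at 4.05% (3.87 to 4.25). All 7 pairs with H3K27me3 fell below the shifts, from 0.241-fold with H3K4me2 to 0.00778-fold with H3K27ac. The H3K36me3/H4K16ac set lay above the shifts with H3K79me2, at 3.89-fold, and below them with the 6 other sets, from 0.748-fold with H3K4me1 to 0.129-fold with H3K27ac and 0.0363-fold with H3K27me3.

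Of the 28 pairs, 16 lay above all 100 shifts and 12 below. By the labels, the marks go with 3 different inputs, although the input used for each call is not given. Among the 9 pairs that share an input, 6 lay above and 3 below; among the 19 that do not, 10 lay above and 9 below. Without H3K27me3, the only mark with its own input, 10 of the 12 pairs with different inputs lay above and 2 below. For H3K27me3 itself the mark and its input cannot be told apart.

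**Figure D1:**
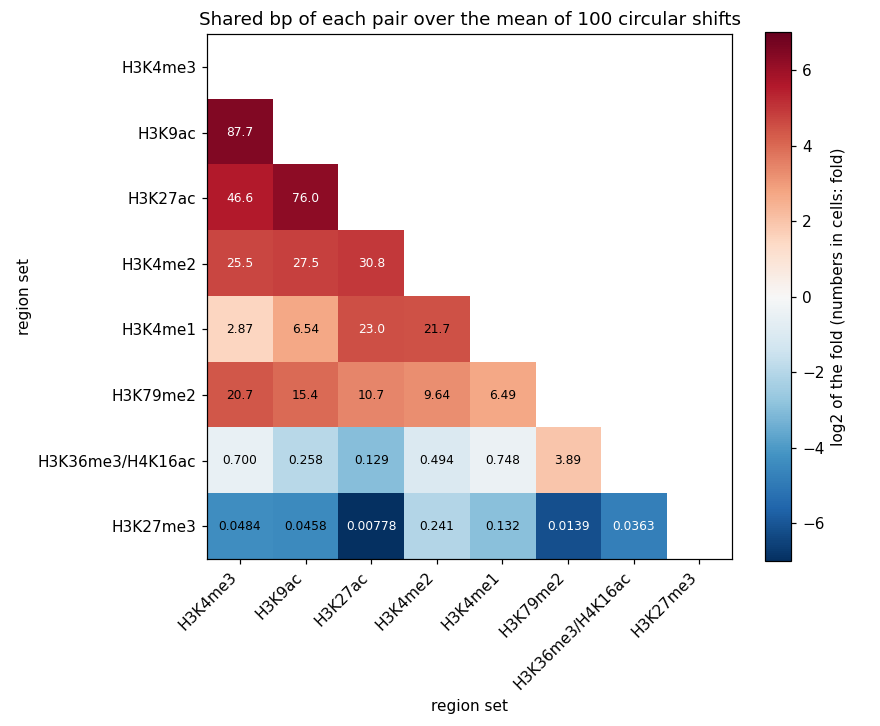
Fold of shared bp for each of the 28 pairs of region sets over the mean of 100 circular shifts; both axes list the sets, colour is the log2 of the fold and the number in each cell is the fold. The H3K27me3 row is below 1 throughout, and the highest cell, 87.7, is H3K4me3 with H3K9ac.

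Most protein-coding genes carried either H3K4me3 or H3K27me3 at an end, and few carried both. H3K4me3 without H3K27me3 was found at 9231 genes (46.2%, 45.5 to 46.9) and H3K27me3 without H3K4me3 at 5477 (27.4%, 26.8 to 28.04). Both marks were at 1022 genes (5.12%, 4.82 to 5.43), against 3336 if the marks were independent, a ratio of 0.306, and 4244 genes had neither. Of the genes with H3K4me3 alone, 98.8% had H3K9ac, 71.3% H3K79me2, 59.1% the H3K36me3/H4K16ac set and 12.3% H3K27ac. Genes with both marks had H3K4me2 in 100% of cases, H3K9ac in 87.7%, H3K79me2 in 37.6% and H3K27ac in 3.23%. Genes with H3K27me3 alone had H3K4me2 in 31.4% and H3K79me2 in 0.365%. The count with both marks depended on the window: it was 1717 within 2.5 kb, 1775 over the whole gene span, 631 when at least 500 bp of a window had to be covered, and 409 among the wider regions. Since either end counts, the marks of such a gene need not share an end. Among genes with no other gene within 5 kb the order of the single classes turned, with 35.7% for H3K4me3 alone and 39.2% for H3K27me3 alone.

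Genes that dividing cells need carried H3K4me3, H3K9ac and H3K4me2 almost without exception. H3K4me3 was at 26 of 26 ribosomal protein genes, 28 of 28 cell cycle and DNA replication genes, 26 of 26 housekeeping metabolism genes and 31 of 32 histone modification enzymes, each at percentile 100 of 10000 random lists. The exception was NSD1, an H3K36 methyltransferase, whose 3450 bp of H3K4me3 lay within 5 kb of its ends but outside the window of 1 kb. H3K79me2 was at 26, 26, 26 and 28 members of these lists. H3K27me3 was at 0 ribosomal protein and 0 housekeeping genes. It was at an end of CCND2 and CDK6, which encode a D-type cyclin and a cyclin-dependent kinase, and of EZH1, a Polycomb methyltransferase; all 3 also had H3K4me3. The widest H3K4me3 cover within 5 kb of the ends was 5550 bp at RPL4 and at PCNA, the replication clamp, 5700 bp at the helicase gene MCM4, 5147 bp at the glycolytic gene PGK1 and 5400 bp at KMT2D, an H3K4 methyltransferase. RPL4 and PKM lie in the 61 to 90 Mb part of chromosome 15 and MCM4 on chromosome 8, where the mean region width of all 8 sets was above that of the rest of chromosome 15 and the median of the other autosomes, respectively. H3K27ac stood above random lists for the housekeeping genes, at 8 of 26 (percentile 100) with PKM, ACTB and PGK1 among them (86.2, within the thresholds, when matched on H3K9ac cover), and not for the ribosomal protein genes, at 3 of 26 (percentile 83.7).

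Haematopoietic regulators and signalling genes carried H3K27ac more often than random lists. H3K4me3 was at 25 of 28 haematopoietic transcription factors (percentile 100) and 19 of 28 signalling and surface genes (percentile 95.9, within random lists). H3K27ac was at 11 and 12 of 28, against means of 1.76 and 1.78 in random lists, both at percentile 100. Against lists matched on H3K9ac cover they were at 85.9, within the thresholds, and 100. H3K27ac covered 4350 bp within 5 kb of the ends of LYL1, 3750 bp at ETV6, 3300 bp at LMO2 and 1950 bp at SPI1, all transcription factors of blood cells. Among surface and signalling genes it covered 4800 bp at SPN, which encodes leukosialin, 2850 bp at the cytokine receptor gene IL2RG, 2550 bp at the progenitor marker CD34 and 2219 bp at RAC2. H3K79me2 covered 97.8% of the body of GATA2 (chromosome 3, 128479422 to 128493201), 95.3% of NFE2 and 78.5% of SPI1. ERG, FLI1 and LMO2 lacked H3K4me3 at both annotated ends, although it covered 2.65%, 3.63% and 11.6% of their bodies. H3K27me3 was at an end of ERG, MECOM and MYC, the last on chromosome 8, and of the receptor genes KIT and CSF2RB. The low H3K27me3 counts of both lists, at percentiles 0.535 and 0.06, were at 10.7 and 7.25 against random runs of neighbouring genes.

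Genes of the BCR-ABL1 and JAK-STAT pathway, which drives this leukaemia, had H3K9ac in 26 of 26 cases, H3K4me3 in 24 and H3K27ac in 10, each at percentile 100, and H3K27me3 in 0. CISH, a feedback inhibitor of cytokine signalling on chromosome 3 (50606489 to 50611774), had the most cover: 8700 bp of H3K4me3, 11962 bp of H3K9ac and 10762 bp of H3K27ac within 5 kb of its ends. SOCS2 and PIM1, also known as targets of STAT5, had 3150 and 2550 bp of H3K27ac. BCL2L1 and PIK3CD were the members without H3K4me3 in the window. BCR (chromosome 22, 23180509 to 23318037) had 3150 bp of H3K4me3 and 39.6% of its body under H3K79me2. ABL1 (chromosome 9, 130713043 to 130887675) had 1050 bp and 3.26%. Neither had H3K27ac or H3K27me3 at an end, and the intervals do not separate the fused from any unfused copy.

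Most genes of mature blood lineages were without H3K4me3. It was at 1 of 28 granulocyte and monocyte genes (VCAN), 1 of 28 erythroid and megakaryocytic genes (ANK1) and 3 of 32 lymphocyte genes (CD4, RAG1 and BCL11B), each at percentile 0. H3K27me3 was at 10, 12 and 12 members, within random lists for all 3. It covered 96.9% of S100A8, 93.2% of FCN1, 83.2% of ANK1 on chromosome 8 and 95.1% of BCL11B. H3K4me1 was at 13 of 28 granulocyte and monocyte genes (percentile 99.6), with 6135 bp within 5 kb of MPO, the gene of myeloperoxidase, 5261 bp at CYBB and 5250 bp at CEBPE, none of which had H3K4me3. That H3K4me1 count was at percentile 96.0 within 2.5 kb of the ends, 78.1 over the whole gene span and 89.7 against random runs. Lymphocyte genes had H3K4me1 at 12 of 32 (percentile 96.6). This rose to 99.88 among wider regions and 98.04 without chromosome 8 and the part of chromosome 15. Erythroid and megakaryocytic genes had it at 9 of 28 (percentile 87.2). Housekeeping metabolism and interferon lists were also above random lists for H3K4me1, at 99.5 and 98.97, so it was not particular to the myeloid list.

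Many genes of other tissues carried H3K27me3. It was at 25 of 28 neuronal genes and 41 of 56 developmental transcription factors, both at percentile 100, and at 18 of 28 germline genes (percentile 99.98) and 16 of 28 liver genes (percentile 99.6). The genes GATA4, LHX2, OTX2 and PAX1, which encode developmental transcription factors, were covered over 100% of their length. GAD1 and GAD2, the enzymes of GABA synthesis, were covered over 95.8% and 92.6%, the liver genes AMBP and HNF4A over 94.5% and 94.9%, and the meiotic gene SYCP1 over 95.1%. SCN2A, SYN1 and SYP were the neuronal genes without it. WT1, a transcription factor gene expressed in many leukaemias, went the other way, with 3150 bp of H3K4me3, 750 bp of H3K27ac and no H3K27me3. H3K4me3 was at 1 neuronal gene (TUBB3), 12 developmental factors, 2 germline genes (TEX14 and TDRD1) and 4 liver genes (APOA1, CPS1, TAT and TF). For CPS1, TAT, TEX14 and TDRD1 it lay beside the gene, with 0% of the body covered. Against random runs of neighbouring genes the H3K27me3 percentiles of the germline and liver lists were 95.8 and 91.4; those of the neuronal and developmental lists kept their side of the threshold.

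Interferon and antigen presentation genes were mixed, with H3K4me3 at 15 of 28 and H3K27me3 at 6, both within random lists. TAP1, CIITA, PSMB9 and CD74 had 3150, 2400, 1950 and 1500 bp of H3K4me3, and H3K27me3 covered 100% of the class II gene HLA-DPA1. Imprinted genes had H3K4me3 at 6 and H3K27me3 at 8 of 17, also within random lists, with 97.6% of IGF2 and 87.3% of L3MBTL1 under H3K27me3. For imprinted genes H3K27me3 was above random lists over the whole gene span, at percentile 99.0, and H3K4me3 below them among wider regions, at 0.175.

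The 4 HOX clusters, which encode factors that set body position and include genes expressed in blood progenitors, differed from one another. In the HOXA cluster (chromosome 7, 27092993 to 27200091), H3K4me3 was at 7 of 11 genes, H3K27ac at HOXA7, HOXA9 and HOXA13, and H3K27me3 at 0, with 0% of the cluster covered. HOXA9 had 6737 bp of H3K4me3 and 2700 bp of H3K27ac within 5 kb of its ends, and 100% of its body under H3K79me2. In the HOXD cluster (chromosome 2, 176087487 to 176190907), H3K27me3 was at 9 of 9 genes and covered 98.6% of the cluster, with H3K4me3 at 0. HOXC (chromosome 12) had H3K27me3 at 8 of 9 genes, all but HOXC10, over 78.7% of the cluster, and H3K4me3 at 0. HOXB (chromosome 17) was split: H3K4me3 was at HOXB2 and HOXB4, and H3K27me3 at 6 of 10 genes, HOXB9 and HOXB13 among them, but not at HOXB2, HOXB3, HOXB4 or HOXB5. H3K4me2 did not separate the clusters in this way. It was at 8 of 11 HOXA, 6 of 10 HOXB, 7 of 9 HOXC and 6 of 9 HOXD genes, all within random lists. It covered 44.7%, 13.3%, 30.5% and 16.1% of these clusters. Among wider regions HOXD was below random lists for H3K4me2, at 0.905. HOXC also had H3K4me1 at 4 and H3K9ac at 3 of 9 genes. The H3K27me3 percentile was 100 for HOXD, 99.97 for HOXC, 96.0 for HOXB and 0.69 for HOXA. Neighbouring genes share regions; against random runs HOXC was at 97.3 and HOXA at 7.06, inside the thresholds, while HOXD stayed above.

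**Figure D2:**
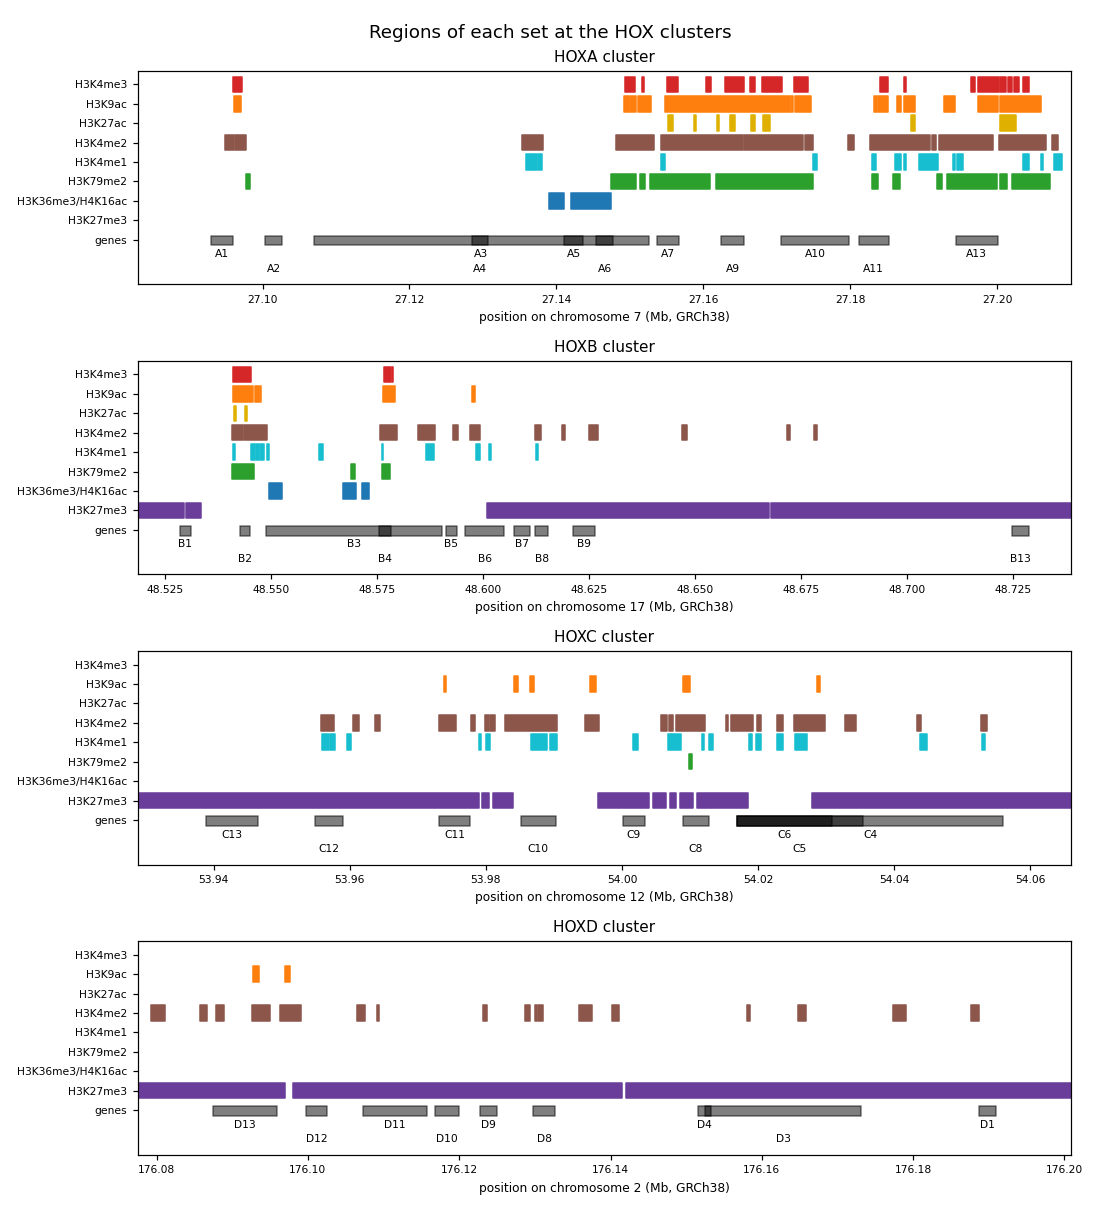
Regions of the 8 sets (coloured bars) and genes (grey bars) over the 4 HOX clusters with 10 kb on either side; the x axis is the position in Mb on GRCh38. H3K27me3 covers 0% of the HOXA cluster and 98.6% of the HOXD cluster.

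Over the 20 lists and 8 sets, 52 of 160 percentiles lay above the upper threshold and 53 below the lower one, where chance gives about 5% outside. Against random runs of neighbouring genes 44 of these calls ended. Genes in such a run can share regions, as those of a HOX cluster do. The other lists mostly hold genes spread over many chromosomes, so runs do not mirror how they are arranged.

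**Figure D3:**
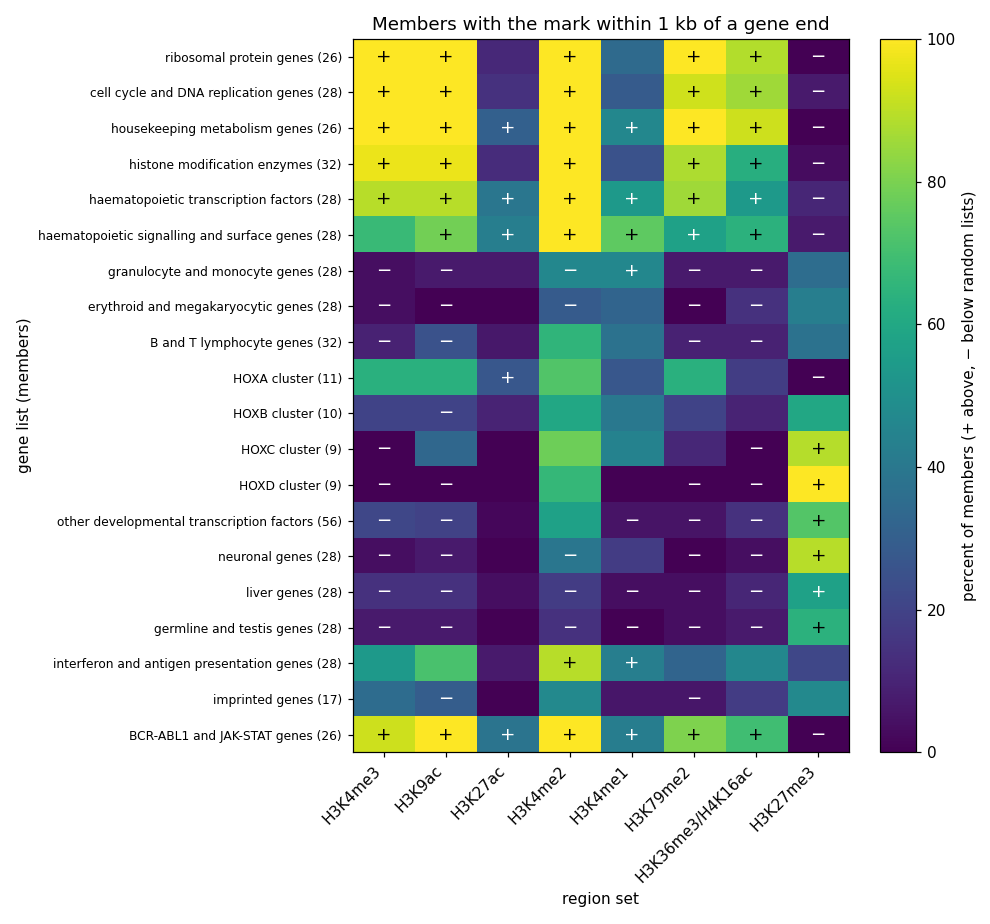
Percent of the members of each fixed gene list (rows, number of members in parentheses) with a region of each set (columns) within 1 kb of an annotated end; plus and minus mark lists above the upper and below the lower percentile threshold of 10000 random lists. H3K27me3 is at 100% of HOXD and 89.3% of neuronal genes and at 0% of ribosomal protein genes.

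Along the bodies of genes, H3K79me2 lay toward the end with H3K4me3. The H3K36me3/H4K16ac set was low at that end and broad over the rest of the gene. The profile used 9004 genes of at least 5 kb with H3K4me3 at exactly 1 end. For each gene that held a mark, the mean position of its cover was taken, which is 50% of the length for even cover. The median over genes was 12.47% for H3K79me2 (6765 genes) and 56.6% for H3K36me3/H4K16ac (7693 genes). Over all 9004 genes, H3K36me3/H4K16ac covered 5.62% of the first twentieth and 50.2% of the last, and H3K79me2 43.9% and 0.985%. Of 16814 genes, 4904 (29.2%, 28.5 to 29.9) were covered over at least 50% of their length by H3K36me3/H4K16ac, 3725 (22.2%, 21.5 to 22.8) by H3K27me3 and 744 (4.43%, 4.12 to 4.75) by H3K79me2, which covered 2318 genes over at least 25% of their length. The haematopoietic transcription factors had the highest median H3K79me2 cover among lists with at least 5 members of this length, 61.5%, followed by the ribosomal protein genes at 56.6%, both at percentile 100. Cell cycle genes led for H3K36me3/H4K16ac at 86.9%, with 96.8% of MCM4, 95.5% of MCM2 and 94.7% of AURKA covered. Developmental factors had a median of 97.6% under H3K27me3 and neuronal genes 68.8%, both at percentile 100. The direction was taken from H3K4me3 itself, so the profile of that mark is fixed by the choice of genes.

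**Figure D4:**
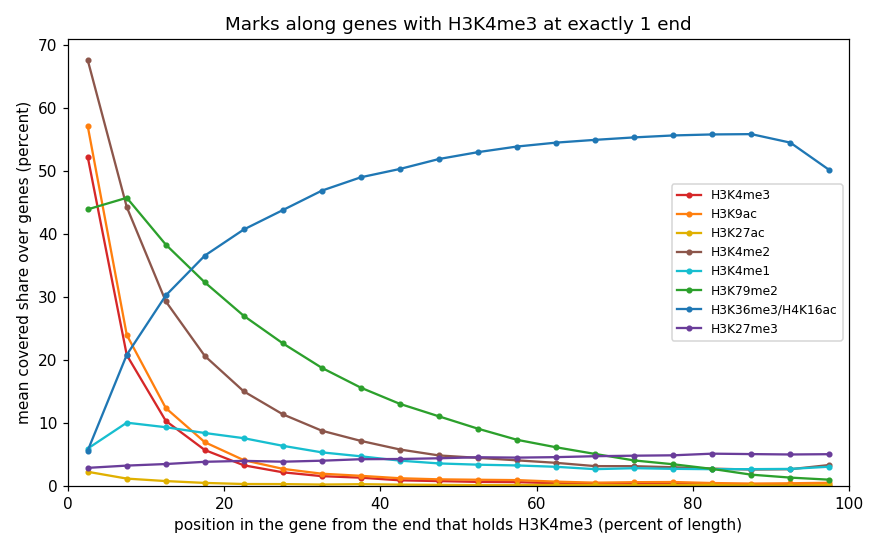
Mean covered share (percent) in 20 equal bins along 9004 genes, from the end that holds H3K4me3 (0) to the other end (100 percent of length), 1 line per region set. H3K79me2 falls from 43.9% to 0.985%. H3K36me3/H4K16ac goes from 5.62% in the first bin to 49.0% in bin 8, and is at 50.2% in the last.

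Away from the ends of genes, in gene bodies or between genes, H3K4me1 marked 29153 regions farther than 2 kb from any annotated gene end, 68.3% of its set. H3K4me2 overlapped 71.5% (71.0 to 72.1) of them, 15.6 times the shifts. H3K9ac overlapped 7.95% (7.64 to 8.26, 5.33-fold) and H3K27ac 3.39% (3.19 to 3.60, 16.9-fold). H3K4me3 was at 1.76% (1.61 to 1.91, 1.62-fold). H3K27me3 overlapped 6.73% (6.45 to 7.02), 0.190 times the shifts, and H3K36me3/H4K16ac 9.10% (8.78 to 9.44), 0.896 times. All 6 lay outside the 100 shifts. The shifted regions could fall at gene ends, which the observed regions exclude, so the folds are not against distal sequence alone. For H3K36me3/H4K16ac the count, 2653, was close to the lowest shift, 2699, and a depletion in distal sequence is not settled. The whole H3K27ac set held 3368 regions. Farther than 5 kb from gene ends, 209 H3K4me1 regions overlapped H3K4me3, against 512 beyond 2 kb.

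The widest H3K4me3 region, 9600 bp, lay at EGFL7 (chromosome 9, 136657351 to 136666950). CD69, a leukocyte activation marker, had 8700 bp, SOCS2 and GATA2 7950 bp each, the repressor gene IRF2BP2 7500 bp and BCL11A, a regulator of fetal globin, 7350 bp. VCPIP1 (9300 bp), the cohesin gene RAD21 (8550 bp), PDE7A (7800 bp) and EIF4EBP1 (7500 bp) completed the 10, and these 4 lie on chromosome 8, where regions were wider. Without chromosome 8 and the 61 to 90 Mb part of chromosome 15, the other 6 were joined by CISH, PGK1, RCC1 and ZEB2.

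The widest H3K27me3 domains, merged over gaps of up to 3 kb, held an annotated end of RGMA (1178000 bp on chromosome 15, 93056501 to 94234500), SLC35F3 (984000 bp), RANBP17 (906000 bp), PHACTR3 (887500 bp), ATP8A2 (833500 bp), ZNF423 (759000 bp), OLFM1 (742500 bp), ATP2B2 (733500 bp), NPVF (706000 bp) and PROK2 (701500 bp). This ranking rested on the gap: 0 of the 10 genes were named without merging and 2 with gaps of up to 10 kb. Of the distal H3K27ac stretches, that with the most covered sequence, 13650 bp, had its middle 158459 bp from the nearest annotated end, of GSDMC on chromosome 8. The next stretch, 9000 bp on chromosome 21 (38474401 to 38499750), lay within ERG. Others were nearest to CIBAR1 (8550 bp, chromosome 8), KLRF1 (8400 bp), TRAF1 (7800 bp), ANKS1A and VSIG4 (7500 bp each), ATP8B4 (7200 bp), TBC1D5 (6450 bp) and HEMK1 (6300 bp). The last, merged from distal regions, spans an annotated end of HEMK1, which lies 634 bp from its middle. That stretch ends at 50603400 on chromosome 3, within 5 kb of CISH. The stretch nearest to KLRF1 starts at 9765001 on chromosome 12, close to the wide H3K4me3 region at CD69, which ends at 9761550. The nearest gene by this rule is therefore not the only neighbour. With H3K27ac at gene ends included, 3 of the 10 were named again.

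All 8 sets covered more of chromosome 8 than of the median autosome, but none covered it most: it ranked between 14 and 19 of 22 autosomes from the lowest. The line is known to be haploid except for chromosome 8 and a part of chromosome 15, each present in 2 copies. H3K4me1 covered 1.91 times as much of chromosome 8 as of the median autosome, H3K27ac 1.76, H3K4me3 1.43, H3K36me3/H4K16ac 1.33, H3K79me2 1.25, H3K9ac 1.15, H3K4me2 1.13 and H3K27me3 1.101, although it had 0.760 times as many genes per Mb. For 6 of the 8 sets it held fewer regions per Mb than the median autosome, and for 7 its median width was the highest of the autosomes. The mean H3K4me3 region was 2060 bp on chromosome 8, against a median of 1015 bp over the means of the other autosomes, and the mean H3K36me3/H4K16ac region 19977 against 6138 bp. By number of regions per Mb the ratio was 0.710 for H3K4me3 and 0.417 for H3K36me3/H4K16ac, so the direction depended on the measure. Chromosome 19, which is rich in genes, had the highest covered ratio for H3K4me3, 3.25, and chromosome 4 the lowest, 0.567. No test was made, as each chromosome has 1 value per mark.

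**Figure D5:**
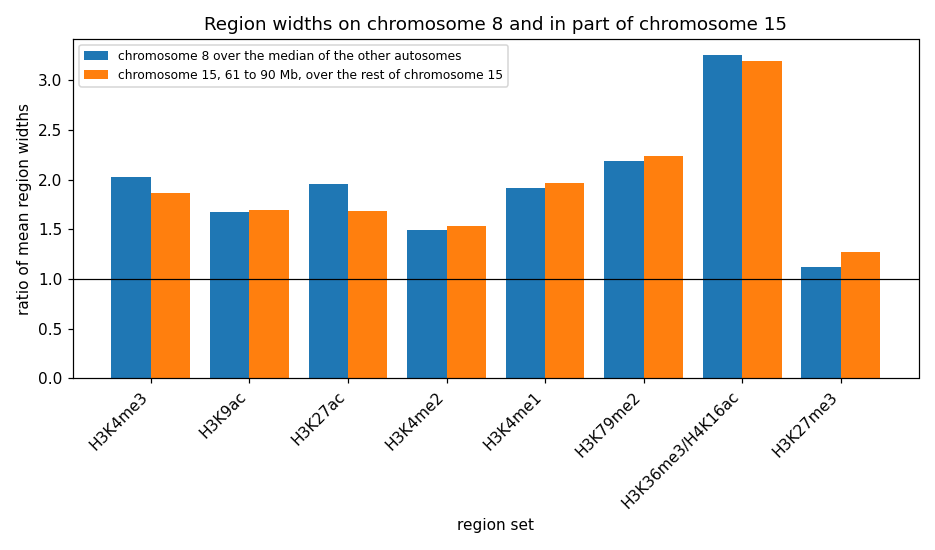
Ratio of mean region widths for each of the 8 sets: chromosome 8 over the median of the other autosomes, and the 61 to 90 Mb part of chromosome 15 over the rest of that chromosome; the line marks a ratio of 1. H3K36me3/H4K16ac reaches 3.26 and 3.19, and H3K27me3 stays at 1.12 and 1.27.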

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

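All tests in this part were chosen after the result was seen.

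The file held 71741 intervals under H3K9me3, a mark for which no sample is among those analysed here. They stood out as a signal outside the main measurement and entered no comparison.

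The labels H3K36me3 and H4K16ac held the same intervals, 45695 of 45695, while no other pair of labels shared more than 4.77% of the smaller set. This is consistent with 1 set of calls having been deposited under 2 names. The set covered the last twentieth of genes 8.93 times as much as the first, which is the profile known for H3K36me3 and suggests calls on that library. Its shared sequence with H3K9ac was 0.258 times that of shifts; as the profile of H4K16ac in these cells is not known from these data, a call on the H4K16ac library cannot be told apart by that value. No biological explanation was tested, and values given for the set cannot be credited to H4K16ac.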

How the results depend on the processing

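The whole gene span, isolated genes, intervals as deposited, shifts without left-out stretches, random runs of neighbouring genes and the removal of chromosome 8 with the 61 to 90 Mb part of chromosome 15 were alternatives chosen after the data were seen. All 28 pairs, by shared bp, and all 8 sets at gene ends kept their direction and call under every alternative run. Of the numbers of overlapping regions in pairs, 6 fell by more than 1.5 times when 50% of the shorter region had to overlap, among them H3K4me3 regions at H3K4me1 from 1696 to 996, H3K9ac at H3K36me3/H4K16ac from 1133 to 369 and H3K27ac at H3K36me3/H4K16ac from 62 to 27. No paired analysis was possible because each mark has 1 library. Transcription starts of all transcripts and lists matched on CpG content were not run, as they need strand and sequence. Depth limits every set but is unknown.

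Keeping regions at or above the median width of their set, fewer by construction, left 1913 regions for H3K27ac, 61620 for H3K27me3, 19266 for H3K36me3/H4K16ac, 23881 for H3K4me1, 28049 for H3K4me2, 8020 for H3K4me3, 16662 for H3K79me2 and 10483 for H3K9ac. It left 409 genes with both marks, 6877 with neither, 8 lists below for H3K4me2 and a median position of 57.3% for H3K36me3/H4K16ac. It left 16529 distal H3K4me1 regions, of which 584 overlapped H3K27ac, 624 H3K9ac, 1355 H3K36me3/H4K16ac, 830 H3K27me3 and 166 H3K4me3. The chromosome 8 ratio was then 2.31 for H3K27ac, 1.57 for H3K36me3/H4K16ac, 2.46 for H3K4me1, 1.32 for H3K4me2, 1.82 for H3K4me3, 1.41 for H3K79me2 and 1.35 for H3K9ac. By number of regions per Mb it turned below 1 for H3K27me3 (0.973), H3K36me3/H4K16ac (0.417), H3K4me2 (0.757), H3K4me3 (0.710), H3K79me2 (0.601) and H3K9ac (0.731), and stood at 1.02 for H3K27ac and H3K4me1; fewer but wider regions give this.

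Merging over 1 kb gave 34163 H3K27me3 and 17553 H3K79me2 regions, and H3K27me3 had 1236351 intervals as deposited on the chromosomes used. Genes with both marks numbered 1717 within 2.5 kb, 631 with at least 500 bp covered and 1775 over the whole span; the cause was not tested. Among isolated genes 35.7% had H3K4me3 only and 39.2% H3K27me3 only. Within 2.5 kb, 5 lists were below for H3K4me1 and 3 for H3K4me2, and over the whole span 1 was below for H3K27ac. Against random runs, 3 lists were above and 3 below for H3K27me3, 1 below for H3K36me3/H4K16ac, 1 above and 1 below for H3K4me1, 2 below for H3K4me2, 5 for H3K4me3, 5 for H3K79me2 and 6 for H3K9ac; of all list calls 44 ended and none reversed. List calls ended and arose in 7 and 9 cases within 2.5 kb, 7 and 8 over the span, 5 and 12 among wider regions and 1 and 1 without chromosome 8 and the part of chromosome 15. Genes of at least 20 kb, fewer by construction, gave 342 covered over 50% by H3K79me2, 3222 by H3K36me3/H4K16ac and 2438 by H3K27me3, with median positions of 9.70% for H3K79me2 and 55.1% for H3K36me3/H4K16ac. H3K79me2 covered 2318 genes over at least 25%. Farther than 5 kb from gene ends, 1529 H3K4me1 regions overlapped H3K9ac and 209 H3K4me3, and by 50% of the shorter region 1750 overlapped H3K36me3/H4K16ac. Of the 10 named genes, 6 were shared for H3K4me3 without chromosome 8 and the part of chromosome 15, 0 for H3K27me3 without merging, 2 with gaps of up to 10 kb, and 3 for H3K27ac with gene ends included; the cause was not tested.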

Other observations

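Of the tests in this part, those on the gene density and the region widths of chromosome 8, on the matched lists and on draws by width were chosen after related results had been seen; those on chromosome 15, on the share of genes with H3K4me3 and on the ratio of H3K9ac widths were written before.

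MYC, singled out after its values were seen, carried active and Polycomb marks on the same gene. On chromosome 8 (127735434 to 127742951), where the mean region width of all 8 sets was above the median of the other autosomes, H3K4me3 covered 70.7% of its body, H3K9ac 64.7% and H3K79me2 78.7%, and H3K27me3 covered 52.6%. The intervals do not separate the copies of this chromosome or single cells, so these marks need not lie on the same copy. Among the genes with both marks that the lists hold, RAG1 had 84.7% of its body under H3K27me3 and H3K4me3 beside it, on 0% of the body.

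Chromosome 8 held more marked sequence than its genes would give. Its gene density, 0.760 times the median autosome, argues against gene content as the cause. In 5 of 5 sets examined the median width on chromosome 8 ranked first or second of 22 autosomes. The 61 to 90 Mb part of chromosome 15 is also present in 2 copies. Regions of the same sets were wider there than in the rest of that chromosome, by a median ratio of 1.83. H3K27me3, not among these sets, ranked 4 by median on chromosome 8 and had a median of 5500 bp both inside and outside the part. Its mean widths were higher in both stretches, with ratios of 1.12 and 1.27, so for that set the result depended on the measure. A hypothesis is that an extra copy of the DNA raised the signal and so widened the called regions, which may also have placed 4 chromosome 8 genes among the 10 widest H3K4me3 regions. A more active chromosome stays open: it ranked 11 of 22 by the share of genes with H3K4me3, 52.9% (49.2 to 56.5) against a median of 52.5%.

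H3K27ac had the fewest regions and was at 12.3% of genes with H3K4me3 alone. H3K9ac regions at gene ends were 1.75 times as wide where H3K27ac was present (2100 against 1200 bp). This ratio was above the 1.25 to 1.375 of 1000 draws weighted by region width plus the median H3K27ac width. It may be that only the strongest sites passed the call, but depth and antibody were not tested. In random lists matched by 5 classes of H3K9ac cover, the ribosomal protein, cell cycle and housekeeping genes together were at percentile 52.5 (15 of 80), and the 2 haematopoietic lists with the BCR-ABL1 and JAK-STAT list, already seen to be high, at percentile 100 (33 of 82). With each gene matched to the 100 nearest in H3K9ac cover, the single lists were at 9.78, 31.6 and 86.2 for ribosomal protein, cell cycle and housekeeping genes, 85.9 for haematopoietic transcription factors, 100 for surface genes and 98.6 for the BCR-ABL1 and JAK-STAT list. A preference of H3K27ac beyond the extent of acetylation thus remains a hypothesis for the latter 2 lists, while the transcription factors were within matched lists. For the BCR-ABL1 and JAK-STAT list the matching was incomplete, with a mean H3K9ac cover of 3498 bp against 3308 bp in its matches. The surface genes had 2222 against 2220 bp.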
